A study of Mus musculus with 20 samples.

How the data were processed

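Gene expression was measured in CD44+CD8+ T cells isolated from lungs of mice carrying 4T1 tumours, a mammary carcinoma line, after intranasal treatment. Biotin-labelled total RNA, extracted with Qiagen reagents, was hybridised to Affymetrix arrays whose probe sets hold perfect-match probes. The 20 arrays fall into 4 groups, with 5 arrays of Saline-CTRL, 6 of SD-101, 5 of SD-101+anti-PD-1 and 4 of SD-101+anti-PD-1+a-CD4. The labels do not say whether the numbered samples of a group came from separate animals, so the p-values measure the spread between these samples.

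The authors deposited log2 expression values per probe set. Per the labels, the authors' processing used affy, RMA and limma and named the genome build mm8, without versions, roles or order. The deposited log2 values ranged from 1.78 to 13.44, with array medians of 3.52 to 3.75. They were used without further normalization. Array data carry no read depth, and precision was limited by the number of arrays per group.

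Of 45141 probe sets, 104 were controls, 28898 were listed with 1 gene symbol, 551 with several symbols, and 15692, controls included, were not listed with a gene. Symbols were checked against a RefSeq table through Entrez identifiers, which matched 28689 probe sets and changed 0 symbols. For 7180 genes with more than 1 probe set, the probe set of the highest mean over all arrays was taken, without regard to group. This gave 17097 genes, with no filter on level.

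All 4 groups were fitted together in limma 3.58.1 under R 4.3.3 with group means as the only terms, and 5 comparisons were taken from the fit with a 2-sided moderated test. A gene was called when its Benjamini-Hochberg adjusted p over all genes was under 0.05, and "rose" and "fell" are used for called genes and lists. Exact permutation tests of 2 groups were 2-sided, and the smallest p they could give was 0.00216 for SD-101 against a group of 5 and 0.00794 for the other comparisons. On simulated data the fit recovered 34.3% to 56.7% of genes changed by 0.5 log2 and 77.6% to 89.6% by 1. Of calls there, not on these arrays, 2.65% to 7.14% were false.

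The 27 gene lists were fixed before the data were examined, as were the comparisons, the test, the rule for naming genes and the first set of other settings. They were cytotoxic effector molecules, inhibitory receptors and exhaustion-linked genes, type I interferon-stimulated genes, interferon-gamma-linked GTPases and antigen presentation, cell cycle and proliferation, memory and naive-associated genes, tissue residency genes, T cell receptor activation and immediate early genes, T cell chemokines and chemokine receptors, TLR9 signalling, IL-2 and STAT5 signalling, glycolysis, oxidative phosphorylation, cholesterol synthesis, heat shock and dissociation stress, T cell identity, CD4 and regulatory T cell markers, gamma-delta T cell markers, NK cell markers, B cell and plasma cell markers, macrophage and monocyte markers, neutrophil markers, dendritic cell markers, lung epithelial and carcinoma markers, endothelial markers, fibroblast markers and erythroid markers. Lists were tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison, with camera at an estimated correlation and with fry, adjusted alike. In SD-101+anti-PD-1 vs Saline-CTRL, 40 simulations reassigned whole residual arrays among the groups. The preset correlation called up to 20 of 27 lists (median 9), and the estimated correlation, fry and the gene test 0. In 100 other simulations the gene test's highest count was at least 162. A call at the preset correlation alone is thus weak evidence, and the adjusted p of both other tests follow in brackets. Of 67 preset calls in 135 list tests, 4 held with an estimated correlation and 26 passed fry. Fry tests whether a list's members moved, on balance, in 1 direction. After the data were seen, 4 lists were added: ciliated airway cell, mast cell, clock output and opposite-phase clock genes. These were adjusted over 4 lists, without fry. The first 3 were drawn from genes among the largest changes and are not independent evidence.

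Named genes were, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall, up to 4 members of smallest p in each list described, and 12 genes fixed singly. Predicted genes, small RNAs and immunoglobulin or T cell receptor segments were given as counts. A list score is the mean log2 value of a list's measured genes on an array. The first set of other settings changed the choice of probe set, the scaling between arrays, the filter on level, the variance model, array weights, the groups in the fit, a block on replicate number and each array in turn. After the data were seen, 3 more settings were added: leaving out the 2 arrays of lowest T cell identity score, scores of 4 other cell types as covariates (cell type scores), and the heat shock score as a covariate. Y-linked genes and Xist are not described.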

Results

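The data are log2 intensities of 17097 genes on 20 arrays of CD44+CD8+ T cells from tumour-bearing mouse lung. SD-101 is a ligand of TLR9, a receptor for microbial DNA, and anti-PD-1 is an antibody against an inhibitory receptor of T cells. The labels do not describe what a-CD4 does, and the group is named here as they name it. The genes of the sort were high in all groups: Cd8a averaged 10.80 and Cd8b1 11.01, while Cd4 averaged 3.13. Transcripts of other lung cells were high as well. Sftpc, the surfactant protein gene of alveolar type 2 cells, averaged 13.14, near the top of the measured range (13.44). The club cell gene Scgb1a1 averaged 11.63, the macrophage gene Lyz2 11.49 and the collagen gene Col3a1 11.45. Intensities of different probe sets do not measure relative amounts of RNA. Cd8a, Cd8b1, Cd44, Cd4 and Tlr9 passed the test in no comparison.

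The number of called genes differed widely between comparisons, from 57 for SD-101 alone to 1218 for SD-101+anti-PD-1+a-CD4, each against saline. Centring each array on its median moved the median log2 fold change of all genes from 0.031 to -0.11 in SD-101+anti-PD-1 vs Saline-CTRL and from 0.0080 to -0.11 in SD-101+anti-PD-1 vs SD-101. Relative to those shifts 346 genes rose and 534 fell, and 407 rose and 269 fell, so the balance of rises and falls depended on the scaling. In SD-101+anti-PD-1+a-CD4 vs Saline-CTRL, where rises were more numerous as deposited, falls were under all 3 other scalings. No called gene named here and no called list changed direction under any of the 3 scalings tried.

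**Figure D1:**
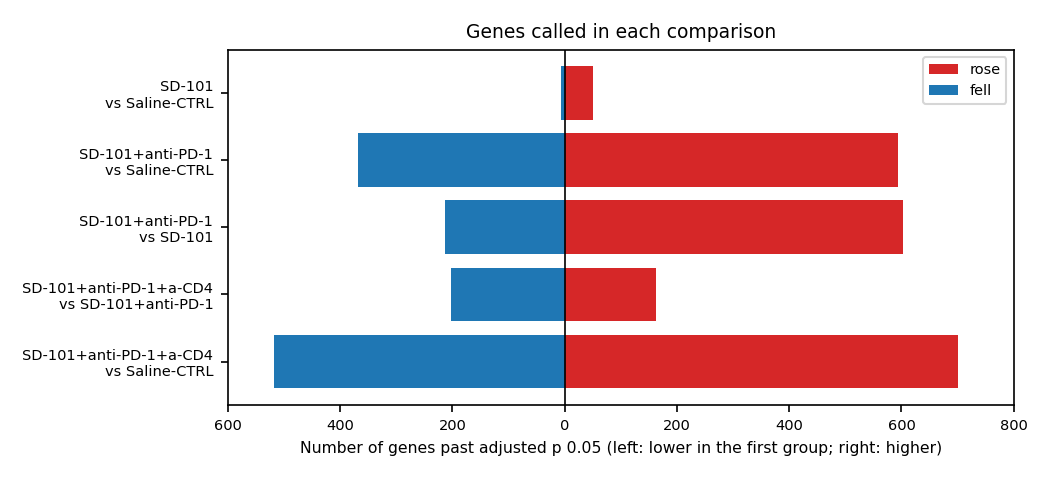
Number of genes with adjusted p under 0.05 in each of the 5 comparisons, as horizontal bars from 0; bars to the right count genes higher in the first-named group and bars to the left genes lower in it. SD-101 vs Saline-CTRL gave 51 rises and 6 falls, and SD-101+anti-PD-1+a-CD4 vs Saline-CTRL 700 rises and 518 falls, on the values as deposited; with arrays centred the latter were 357 and 534.

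SD-101 vs Saline-CTRL asked what the inhaled TLR9 ligand alone changed (6 against 5 arrays). Interferon-induced genes were higher with SD-101, among them Mx1 (log2 fold change 1.999, SE 0.34, adjusted p = 0.0145), which encodes an antiviral GTPase, and Rsad2 (1.64, SE 0.26, adjusted p = 0.01), which encodes viperin. Gzmb, a protease of cytotoxic granules, rose by 1.88 (SE 0.39, adjusted p = 0.0441). The largest rises were of antibody genes, Ighm (3.599, SE 0.64, adjusted p = 0.0172) and Jchain (3.49, SE 0.59, adjusted p = 0.0145). Mx1, Rsad2, Gzmb and Jchain were above every saline array in 6 of 6 SD-101 arrays and Ighm in 5 of 6. With each array left out in turn, Gzmb lost its call in 10 of 11 (adjusted p up to 0.127, without Saline-CTRL replicate 1), and Ighm in 1 (0.0545, without Saline-CTRL replicate 3). The mast cell proteases Cma1 (2.57) and Mcpt2 (2.40) rose too. So did the interferon-inducible Ubd (2.40), Ifi44l (2.35) and Cxcl9 (2.34) and Eaf2 (2.25). Per2, a component of the circadian clock, fell by 0.88, and Tef (-0.86) and Nr1d2 (-0.67), which follow the clock, fell as well. Per2 lost its call in 9 of these 11 fits (adjusted p up to 0.103, without Saline-CTRL replicate 3). Klf9 (-1.13), Cytl1 (-1.46) and Slc12a5 (-0.81) were the other falls called. Single arrays left out ended the calls of Mcpt2, Klf9 and Slc12a5 (in 8, 5 and 8 of 11 fits, adjusted p up to 0.118, 0.0849 and 0.114 without Saline-CTRL replicate 1) and Cxcl9, Cytl1 and Nr1d2 (in 8, 9 and 8 of 11 fits, adjusted p up to 0.161, 0.145 and 0.117 without Saline-CTRL replicate 3). With 1 array left out, calls ended for Eaf2 (in 8 of 11 fits, adjusted p up to 0.128 without SD-101 replicate 3).

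Of 28 measured type I interferon-stimulated genes, 10 rose, 0 fell and 18 passed neither way, and 26 rose when adjusted within the list. Their mean log2 shift was 0.87 (camera adjusted p = 1.2e-36). The call held, at adjusted p = 0.0184 with an estimated correlation and fry adjusted p = 0.00101. Isg20 (0.88) and Zbp1 (1.18) were further members that rose. Among interferon-gamma-linked genes 7 of 26 rose, 19 did not pass, and 23 rose when adjusted within the list. Their mean shift was 0.72 (camera adjusted p = 5.19e-32, 0.00584 with estimated correlation, 1.25e-04 by fry). The examples were the GTPase genes Igtp (0.95), Iigp1 (1.48), Irgm1 (0.83) and Gbp3 (0.85). In the TLR9 signalling list 1 of 16 rose, Irf7 (1.25), which is also an interferon-stimulated gene. The list's mean was 0.22 (camera adjusted p = 0.0425, 0.18 with estimated correlation, 0.0375 by fry). It was 0.21, 0.22, 0.22, 0.20 and 0.15 with Saline-CTRL replicates 1, 4 and 5 and SD-101 replicates 3 and 4 left out in turn (adjusted p = 0.0538, 0.0656, 0.0943, 0.0802 and 0.126). With 4 cell type scores as covariates it turned to -0.00042, and with the heat shock score it was 0.23 (camera adjusted p = 0.0612). Fits without 1 array lost the calls of Irf7 and Gbp3 (in 8 and 2 of 11 fits, adjusted p up to 0.114 and 0.0741 without Saline-CTRL replicate 1).

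B and plasma cell markers shifted by 1.14 (camera adjusted p = 1e-12, 0.0433 with estimated correlation, 0.00643 by fry). Of 17, 2 rose, and 11 when adjusted within the list. NK cell markers shifted by 0.92 (camera adjusted p = 1.91e-07, 0.0433 with estimated correlation, 0.00903 by fry), and 1 of 12 rose, Ncr1 (1.86). Leaving out 1 array ended the calls of Ncr1 (in 8 of 11 fits, adjusted p up to 0.146 without Saline-CTRL replicate 1). Macrophage and monocyte markers had a mean of 0.95 with none of 21 called (camera adjusted p = 4.8e-09, 0.18 with estimated correlation, 0.071 by fry). The mean was 0.57 with SD-101 replicate 4 left out (adjusted p = 4.24e-06). Dendritic cell markers averaged 0.51 with none of 11 called (camera adjusted p = 0.0154, 0.394 with estimated correlation, 0.254 by fry). This mean was 0.45, 0.48, 0.42 and 0.26 with Saline-CTRL replicates 2 and 5 and SD-101 replicates 3 and 4 left out in turn (adjusted p = 0.0588, 0.0686, 0.0612 and 0.188). Endothelial markers averaged -0.62 with none of 14 called (camera adjusted p = 1.22e-05, 0.375 with estimated correlation, 0.254 by fry). The value was -0.36 with SD-101 replicate 6 left out (adjusted p = 0.0035). With 4 cell type scores as covariates the NK and B cell means were 0.26 and 0.53 (camera adjusted p = 0.149 and 0.044), and the dendritic mean turned to -0.10. A further 7 immunoglobulin segments rose.

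Other T cell and metabolic groups had few called members in SD-101 vs Saline-CTRL, and all called lists among them except cholesterol synthesis had positive means. The cytotoxic list averaged 0.58 with Gzmb alone of 27 rising, 7 adjusted within the list (camera adjusted p = 1.1e-08, 0.18 with estimated correlation, 0.0535 by fry). Inhibitory receptors averaged 0.64 with none of 20 called (camera adjusted p = 1.23e-05, 0.375 with estimated correlation, 0.216 by fry). T cell chemokines and receptors averaged 0.56 with none of 18 called (camera adjusted p = 4.54e-05, 0.276 with estimated correlation, 0.141 by fry). Cell cycle genes averaged 0.51 with none of 41 called, although 41 had positive values (camera adjusted p = 6.86e-14, 0.276 with estimated correlation, 0.141 by fry). That was 0.32 with Saline-CTRL replicate 3 left out (adjusted p = 6.48e-07). Tissue residency genes averaged 0.29 with 1 of 19 rising, Isg20 (camera adjusted p = 0.0103, 0.394 with estimated correlation, 0.236 by fry). The shift was 0.19 with Saline-CTRL replicate 1 left out (adjusted p = 0.0627). T cell identity genes averaged 0.27 with none of 13 called (camera adjusted p = 0.0243, 0.615 with estimated correlation, 0.529 by fry). This shift was 0.11, 0.22 and 0.22 with Saline-CTRL replicates 1 and 4 and SD-101 replicate 6 left out in turn (adjusted p = 0.276, 0.12 and 0.0846). CD4 and regulatory markers averaged 0.30 with none of 12 called (camera adjusted p = 0.0411, 0.394 with estimated correlation, 0.221 by fry). The mean value was 0.22, 0.27, 0.32, 0.27, 0.29, 0.24 and 0.25 with Saline-CTRL replicates 1, 2 and 5 and SD-101 replicates 3, 4, 5 and 6 left out in turn (adjusted p = 0.0899, 0.0678, 0.0943, 0.0802, 0.0606, 0.124 and 0.0965). Cholesterol synthesis genes averaged -0.22 with none of 16 called (camera adjusted p = 0.00243, 0.394 with estimated correlation, 0.406 by fry). That value was -0.047 with Saline-CTRL replicate 2 left out (adjusted p = 0.48). Oxidative phosphorylation genes averaged 0.067 with none of 28 called (camera adjusted p = 0.0103, 0.394 with estimated correlation, 0.168 by fry). This value was 0.048 with SD-101 replicate 5 left out (adjusted p = 0.0734). With cell type scores as covariates the cytotoxic, oxidative phosphorylation and cell cycle means were 0.15, 0.014 and 0.30 (camera adjusted p = 0.738, 0.893 and 0.0191), and those of inhibitory receptors, chemokines, residency, T cell identity and CD4 markers turned to -0.12, -0.044, -0.015, -0.056 and -0.021. Of the genes fixed singly, Cd274, the gene of PD-L1, had a value of 0.95 (adjusted p = 0.0986; exact p = 0.00216, the smallest possible here). Pdcd1, the gene of PD-1, had a value of 1.17 (adjusted p = 0.426; exact p = 0.0411). The other 9 not called had adjusted p of 0.348 to 0.994.

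In all, 51 genes rose and 6 fell with SD-101 (1414 at an unadjusted p under 0.05). The count was 27, 35, 28 and 34 without Saline-CTRL replicates 1, 2, 3 and 4, and 26, 29 and 25 without SD-101 replicates 3, 4 and 5. It was 36 with arrays centred, 10 with only these groups fitted, 119 with array weights, 99 with the heat shock score as a covariate and 0 in limma with 4 cell type scores as covariates (1192 unadjusted). Of 25 called genes named here 12 stayed called whichever array was left out, and 12 lost the call without Saline-CTRL replicate 1. With those 4 scores 5 of 15 list calls held.

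SD-101+anti-PD-1 vs Saline-CTRL asked what the ligand with PD-1 blockade changed (5 against 5 arrays). Interferon-stimulated genes were higher: Rsad2 (log2 fold change 2.35, SE 0.27, adjusted p = 1.93e-04), Isg20 (1.42, SE 0.16, adjusted p = 1.78e-04), which encodes an exonuclease, and Ifit1 (1.97, SE 0.27, adjusted p = 2.74e-04) rose. The granzyme genes Gzmb (2.09, SE 0.41, adjusted p = 0.0039) and Gzmk (1.88, SE 0.30, adjusted p = 8.54e-04) rose too. These 5 genes were above every saline array in 5 of 5 arrays. S1pr1, the receptor by which T cells leave tissues, fell by 1.33 (SE 0.24, adjusted p = 0.00234) and was below every saline array in 5 of 5. The 8 largest falls were Gpihbp1 (-5.21), Aplnr (-5.03), Clec14a (-4.47) and Tek (-4.46), followed by Plvap (-4.45), Clec1a (-4.34), Sema3g (-4.18) and Acer2 (-4.04). The largest rise was of Pigr (3.97, SE 0.76), the epithelial transporter of secreted antibody.

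Type I interferon-stimulated genes rose in 18 of 28 cases, with 10 not called and 24 risen when adjusted within the list. The mean was 1.12 (camera adjusted p = 3.02e-25, 0.0779 with estimated correlation, 1.03e-04 by fry). Usp18 (1.81) was a further member that rose. Interferon-gamma-linked genes rose in 11 of 26 cases, 17 when adjusted within the list. Their mean was 0.61 (camera adjusted p = 1.11e-12, 0.0876 with estimated correlation, 1.55e-04 by fry). Among cytotoxic genes 5 of 27 rose, 6 when adjusted within the list, including Klrk1 (1.49) and Tbx21 (1.36). The mean of that list was 0.43 (camera adjusted p = 0.0384, 0.903 with estimated correlation, 0.219 by fry). That shift was 0.31, 0.43, 0.43, 0.36 and 0.39 with Saline-CTRL replicates 1, 4 and 5 and SD-101+anti-PD-1 replicates 3 and 5 left out in turn (adjusted p = 0.184, 0.0514, 0.0589, 0.105 and 0.209). With cell type scores as covariates it was -0.032. Memory and naive-associated genes fell in 4 of 19 cases, 5 when adjusted within the list: S1pr1, Klf2 (-0.97), Id3 (-1.06) and Klf3 (-0.53). Their mean was -0.24 (camera adjusted p = 0.00429, 0.501 with estimated correlation, 0.244 by fry). In the cell cycle list 2 of 41 rose, Ccne1 (0.91, adjusted p = 0.0265) and Mki67 (0.88, adjusted p = 0.0473), and 1 when adjusted within the list. Its mean was 0.42 (camera adjusted p = 0.00123, 0.921 with estimated correlation, 0.345 by fry), 0.22 with cell type scores (camera adjusted p = 0.967) and 0.81 with the heat shock score (camera adjusted p = 3.09e-13) as covariates. The list mean was 0.34 and 0.23 with Saline-CTRL replicates 2 and 3 left out in turn (adjusted p = 0.0561 and 0.162). Left out in turn, single arrays ended the call of Mki67 in 9 of 10 fits (adjusted p up to 0.126, without Saline-CTRL replicate 3) and of Ccne1 in 5 (0.0903, without Saline-CTRL replicate 3). Calls that ended with 1 array left out were those of Klf2, Id3 and Klf3 (in 3, 6 and 8 of 10 fits, adjusted p up to 0.0692, 0.0973 and 0.13 without Saline-CTRL replicate 3) and Tbx21 (in 2 of 10 fits, adjusted p up to 0.0547 without SD-101+anti-PD-1 replicate 3).

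Immediate early and heat shock genes were lower with SD-101+anti-PD-1 than with saline. The T cell receptor activation list had 8 of 28 members falling, 9 when adjusted within the list, and none rising. Its mean was -0.46 (camera adjusted p = 4.5e-06, 0.417 with estimated correlation, 0.0645 by fry). With the heat shock score, which shares genes with it, as a covariate the mean turned to 0.093. Those with the smallest p were Egr1 (-1.33), Dusp1 (-1.31), Fos (-0.66) and Nr4a1 (-1.84), genes also induced by handling of tissue. The heat shock and dissociation list fell in 7 of 17 members, 10 when adjusted within the list, with Ier2 (-1.05) and Jun (-1.05) as examples. Its mean was -0.76 (camera adjusted p = 1.86e-09, 0.112 with estimated correlation, 0.00446 by fry). Cell type scores as covariates gave the 2 lists -0.77 and -0.48 (camera adjusted p = 5.33e-10 and 3.57e-05). The 18S ribosomal RNA control probe set near the 5' end averaged 12.11 ± 0.19 (SD, n = 5) with SD-101+anti-PD-1 and 11.68 ± 0.29 (SD, n = 5) with saline. Saline-CTRL replicates 1 and 2, at 11.99 and 11.998, lay near the former, and replicates 3 to 5 were at 11.44 to 11.50.

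Endothelial markers fell in 13 of 14 cases, 14 when adjusted within the list, with Cdh5 (-3.87), Vwf (-3.49), Cldn5 (-3.35) and Calcrl (-3.28). The endothelial score was 6.42 ± 0.38 (SD, n = 5) against 9.27 ± 0.72 (SD, n = 5) with saline. The mean shift was -2.86 (camera adjusted p = 1.75e-27, 0.0617 with estimated correlation, 9.51e-05 by fry). Ciliated airway cell genes, a list added after the data were seen, rose in 12 of 13 cases, with Ccdc153 (3.85), Tmem212 (3.62) and Cfap126 (3.13). The mean was 2.47 (camera adjusted p = 4.04e-18, 0.0259 with estimated correlation), which is not independent evidence since the list was drawn up from such genes. Cxcl17 (3.36), Slc26a4 (3.48), Vnn1 (2.97) and Ly6i (3.85) were the other largest rises. Lung epithelial markers averaged 0.88 with 1 of 21 rising, Cldn7 (1.51), and 9 when adjusted within the list. The test gave camera adjusted p = 1.62e-04, 0.53 with estimated correlation, 0.0645 by fry. With the heat shock score as a covariate this mean turned to -0.048. Fibroblast markers averaged 0.71 with Col1a1 (2.29), Col1a2 (0.48) and Col3a1 (1.24) rising of 14 (camera adjusted p = 0.00161, 0.641 with estimated correlation, 0.116 by fry). It was 0.44 with Saline-CTRL replicate 5 left out (adjusted p = 0.0589). With the heat shock score as a covariate it turned to -0.045. B and plasma cell markers averaged 0.87 with 5 of 17 rising, 9 when adjusted within the list, among them Fcer2a (1.69) and Jchain (2.85). The test gave camera adjusted p = 6.99e-04, 0.501 with estimated correlation, 0.0516 by fry. Cell type scores as covariates left B cell and fibroblast means of 0.37 and 0.18 (camera adjusted p = 0.973 and 0.764). Besides, 7 immunoglobulin segments rose. Single arrays left out ended the calls of Cldn7 (in 4 of 10 fits, adjusted p up to 0.0714 without Saline-CTRL replicate 3) and Col1a2 (in 7 of 10 fits, adjusted p up to 0.109 without SD-101+anti-PD-1 replicate 2). With 1 array left out, calls ended for Col3a1 (in 8 of 10 fits, adjusted p up to 0.119 without Saline-CTRL replicate 4).

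In SD-101+anti-PD-1 vs Saline-CTRL 594 genes rose and 368 fell (3183 at an unadjusted p under 0.05), and 346 and 534 with arrays centred. Pdcd1 had a value of 1.36 (adjusted p = 0.0787; exact p = 0.00794, the smallest possible here) and Cd274 0.76 (adjusted p = 0.0672; exact p = 0.0159). The other 8 fixed genes not called had adjusted p of 0.452 to 0.995. The count was 1531, 553 and 612 without Saline-CTRL replicates 2, 3 and 4 and 618 and 625 without SD-101+anti-PD-1 replicates 3 and 4. It was 566 among genes above the median level, 1953 with array weights, 1 with the heat shock score as a covariate (1664 unadjusted) and 0 in limma with cell type scores as covariates (1149 unadjusted). Of 52 genes checked, not all named, 41 kept the call with any 1 array left out, and 10 lost it without Saline-CTRL replicate 3. Cell type scores as covariates left 5 of 9 list calls.

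SD-101 and SD-101+anti-PD-1 shared 46 genes called in the same direction against saline, 44 rising and 2 falling, such as Mx1, Rsad2, Gzmb and Jchain. Simulated unchanged groups shared a median of 0 and at most 1 with the same saline arrays on both sides, a value without real effects. Independent calls would share 1.77 rising and 0.129 falling genes, a value without shared arrays, so the excess over either does not measure a shared effect. With the saline arrays split between the comparisons the median over 20 splits was 6.5 (range 1 to 35). Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.405 where simulated unchanged groups against the same saline arrays gave 0.0254 to 0.911 (median 0.548). Their covariance was 0.0572 against a simulated mean of 0.03. The overlap was 23, 29, 24 and 28 without Saline-CTRL replicates 1, 2, 3 and 4. It was 20, 26 and 21 without SD-101 replicates 3, 4 and 5, 26 without SD-101+anti-PD-1 replicate 3 and 28 with arrays centred.

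**Figure D2:**
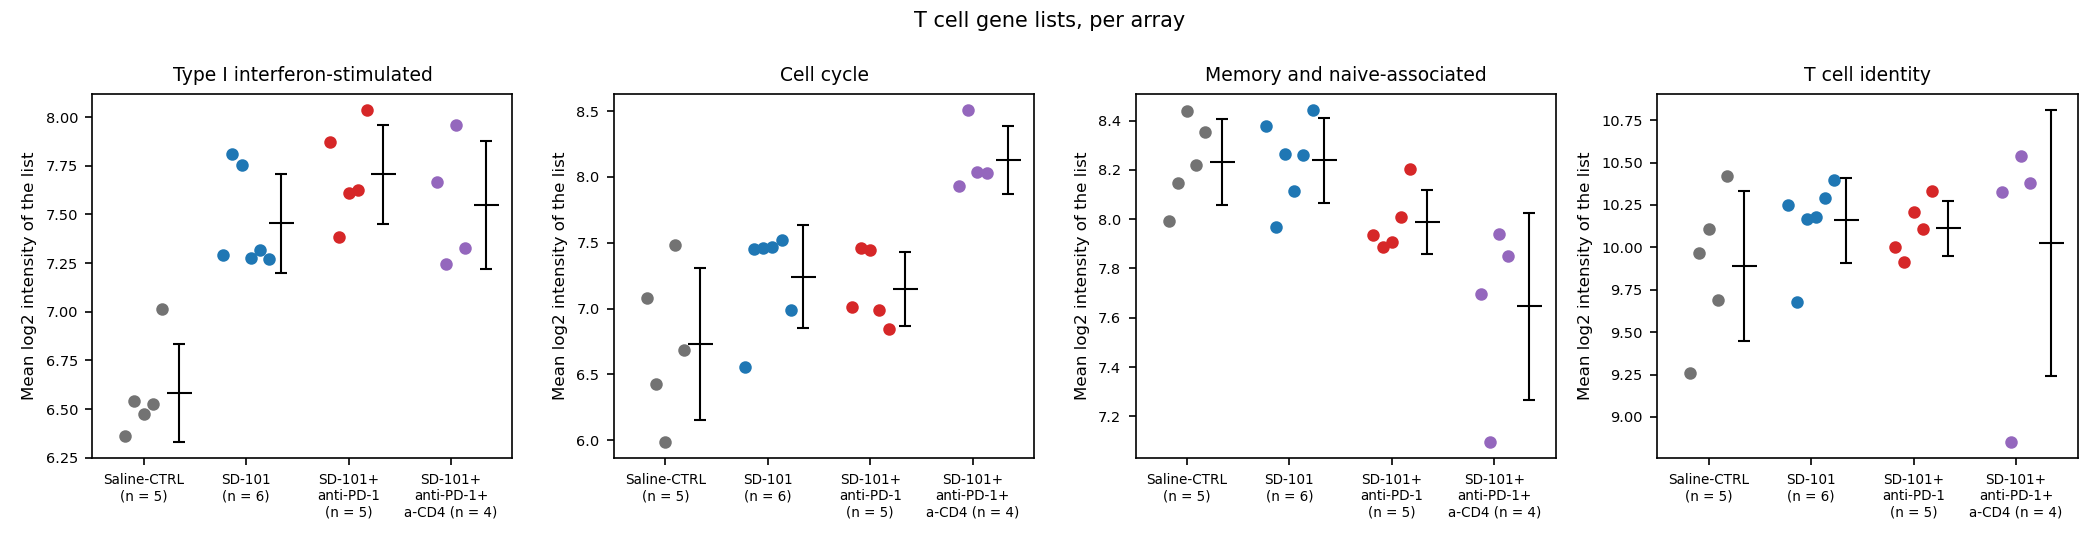
Mean log2 intensity per array (vertical axis) of 4 T cell gene lists, by group; each point is an array, and the black bar is the group mean with its SD. The interferon-stimulated score averaged 6.58 with saline and 7.71 with SD-101+anti-PD-1, and the cell cycle score was highest with SD-101+anti-PD-1+a-CD4, at 8.13.

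SD-101+anti-PD-1 vs SD-101 asked what PD-1 blockade added to the ligand (5 against 6 arrays). The interferon-stimulated Ifit1 (log2 fold change 0.92, SE 0.25, adjusted p = 0.045) and Isg20 (0.54, SE 0.15, adjusted p = 0.0452) rose. They were above every SD-101 array in 3 of 5 and 5 of 5 arrays. S1pr1 (-0.89, SE 0.23, adjusted p = 0.0346) and Klf2 (-0.88, SE 0.23, adjusted p = 0.0344), the transcription factor that drives S1pr1, fell, below every SD-101 array in 5 of 5 and 4 of 5. Which cells gave these falls was not tested. Ncr1, a receptor of NK cells, fell by 1.77 (SE 0.39, adjusted p = 0.0144; lower in 5 of 5). With each array left out in turn, Ifit1 lost its call in 8 of 11 (adjusted p up to 0.119, without SD-101+anti-PD-1 replicate 1). Isg20, S1pr1 and Klf2 lost theirs in as many (adjusted p up to 0.121, without SD-101+anti-PD-1 replicate 3, and 0.0924 and 0.0906, without SD-101+anti-PD-1 replicate 1). Among the largest changes Tmem212 (3.40), Ccdc153 (3.09), Pifo (2.80) and Cfap126 (2.72) rose, as did Ak7 (2.65), Nme5 (2.56), Cyp2f2 (2.69) and Cxcl17 (2.45). Aplnr (-4.50), Gpihbp1 (-4.26), Tek (-3.62) and Sox17 (-3.58) fell together with Clec1a (-3.56), Plvap (-3.54) and Clec14a (-3.51) and the mast cell protease Mcpt2 (-3.601). Fits without 1 array lost the calls of Cyp2f2 (in 9 of 11 fits, adjusted p up to 0.121 without SD-101+anti-PD-1 replicate 4) and Cxcl17 (in 5 of 11 fits, adjusted p up to 0.0701 without SD-101+anti-PD-1 replicate 1).

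Of 28 interferon-stimulated genes, Ifit1 and Isg20 rose and 26 did not pass. Their mean was 0.25 (camera adjusted p = 0.0116, 0.676 with estimated correlation, 0.387 by fry). The mean was 0.17 with SD-101+anti-PD-1 replicate 5 left out (adjusted p = 0.252). It was 0.46 with cell type scores and 0.22 with the heat shock score as covariates (camera adjusted p = 2.97e-04 and 0.0556). The immediate early list had 7 of 28 members falling, 10 when adjusted within the list, among them Junb (-1.06), Dusp1 (-0.88), Nr4a1 (-1.43) and Fos (-0.48). Its mean was -0.46 (camera adjusted p = 8.38e-06, 0.427 with estimated correlation, 0.139 by fry). It turned to 0.021 with the heat shock score as a covariate. The heat shock list had 6 of 17 falling, 11 when adjusted within the list, with Hspa1b (-1.95), Ier2 (-0.82) and Jun (-0.80). The mean there was -0.66 (camera adjusted p = 6.18e-09, 0.24 with estimated correlation, 0.0141 by fry), and -0.26 with cell type scores (camera adjusted p = 2.97e-04). Memory genes averaged -0.25, with S1pr1 and Klf2 alone of 19 falling (camera adjusted p = 0.00643, 0.468 with estimated correlation, 0.254 by fry). Inhibitory receptor genes averaged -0.44 with 1 of 20 falling, Nr4a1 (camera adjusted p = 0.0029, 0.593 with estimated correlation, 0.425 by fry). Cholesterol synthesis genes averaged 0.34 with none of 16 called (camera adjusted p = 0.0132, 0.608 with estimated correlation, 0.254 by fry). This mean was 0.30 and 0.29 with SD-101 replicate 1 and SD-101+anti-PD-1 replicate 1 left out in turn (adjusted p = 0.0599 and 0.0566). With cell type scores as covariates it turned to -0.24. The heat shock score as a covariate left means of -0.19 and 0.055 for inhibitory receptor and cholesterol synthesis genes (camera adjusted p = 0.129 and 0.801). The 18S control near the 5' end averaged 12.11 ± 0.19 (SD, n = 5) with SD-101+anti-PD-1 and 11.49 ± 0.18 (SD, n = 6) with SD-101. Leaving out 1 array ended the calls of Nr4a1, Dusp1, Ier2 and Jun (in 6, 6, 1 and 8 of 11 fits, adjusted p up to 0.0718, 0.0756, 0.0544 and 0.0904 without SD-101+anti-PD-1 replicate 4) and Junb, Fos and Hspa1b (in 3, 6 and 5 of 11 fits, adjusted p up to 0.0646, 0.0708 and 0.075 without SD-101+anti-PD-1 replicate 3).

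Endothelial markers fell in 11 of 14 cases with a mean of -2.24 (camera adjusted p = 5.14e-21, 0.163 with estimated correlation, 0.00106 by fry). Ciliated genes, the added list, rose in 12 of 13 with a mean of 2.24 (camera adjusted p = 7.66e-18, 0.0137 with estimated correlation). Lung epithelial markers had Epcam (1.25) and Cldn7 (1.38) rising of 21, 12 when adjusted within the list. Their mean was 0.94 (camera adjusted p = 3.21e-07, 0.427 with estimated correlation, 0.0442 by fry). NK cell markers averaged -0.81 with Ncr1 alone of 12 falling (camera adjusted p = 2.17e-04, 0.296 with estimated correlation, 0.0442 by fry). Macrophage markers averaged -0.89 with C1qa (-1.37) falling of 21 (camera adjusted p = 1.43e-04, 0.468 with estimated correlation, 0.217 by fry). The value was -0.51 with SD-101 replicate 4 left out (adjusted p = 0.00425). Dendritic cell markers averaged -0.70 with none of 11 called (camera adjusted p = 6.06e-04, 0.427 with estimated correlation, 0.139 by fry). That was -0.45 with SD-101 replicate 4 left out (adjusted p = 0.00965). Fibroblast markers averaged 0.59 with Col1a2 (0.46) rising of 14 (camera adjusted p = 0.00235, 0.593 with estimated correlation, 0.214 by fry). They turned to -0.21 with cell type scores and -0.066 with the heat shock score as covariates, where the dendritic mean was -0.021 and -0.31 (camera adjusted p = 0.439 and 0.0455) and the epithelial, with the latter, 0.14 (camera adjusted p = 0.801). Calls that ended with 1 array left out were those of C1qa (in 9 of 11 fits, adjusted p up to 0.106 without SD-101+anti-PD-1 replicate 4) and Epcam and Cldn7 (in 2 and 8 of 11 fits, adjusted p up to 0.0691 and 0.107 without SD-101+anti-PD-1 replicate 1). Single arrays left out ended the calls of Col1a2 (in 10 of 11 fits, adjusted p up to 0.123 without SD-101+anti-PD-1 replicate 2).

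Altogether 602 genes rose and 214 fell between these groups (3122 at an unadjusted p under 0.05), and none of the 12 fixed genes passed (adjusted p 0.577 to 0.99). The count was 405, 373 and 522 without SD-101 replicates 3, 4 and 5 and 344, 539, 422 and 317 without SD-101+anti-PD-1 replicates 1, 2, 3 and 4. It was 325 above the median level, 2760 with array weights, 1332 with only these groups fitted, 3 with the heat shock score as a covariate (871 unadjusted) and 0 in limma with cell type scores (890 unadjusted). Of 36 genes checked, not all named, 19 kept the call with any 1 array left out, and 17 lost it without SD-101+anti-PD-1 replicate 4. Cell type scores as covariates left 6 of 9 list calls and the heat shock score 5 of 11.

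**Figure D3:**
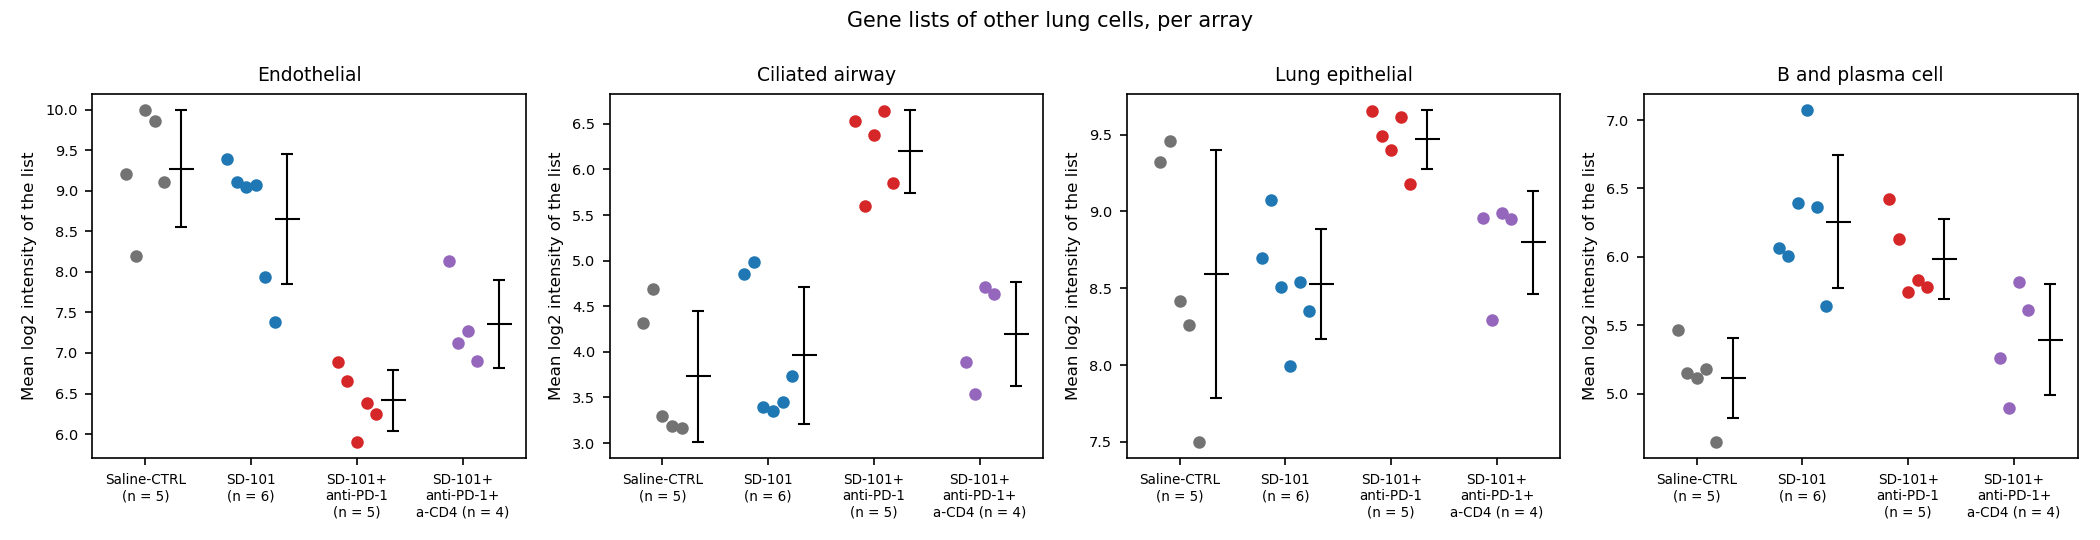
Mean log2 intensity per array (vertical axis) of 4 marker lists of other lung cells, by group; each point is an array, and the black bar is the group mean with its SD. The endothelial score averaged 9.27 with saline, 6.42 with SD-101+anti-PD-1 and 7.36 with SD-101+anti-PD-1+a-CD4.

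SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1 asked what adding a-CD4 changed (4 against 5 arrays). Genes of cell division were higher with a-CD4: Kif11 (log2 fold change 1.70, SE 0.26, adjusted p = 0.00493), a mitotic motor, Ncapg (1.64, SE 0.36, adjusted p = 0.0253), a condensin subunit, and Rrm1 (0.88, SE 0.18, adjusted p = 0.0181), a subunit of ribonucleotide reductase, rose. These 3 and Foxp3 were above every SD-101+anti-PD-1 array in 4 of 4 arrays. Foxp3, the transcription factor of regulatory T cells, rose by 0.63 (SE 0.14, adjusted p = 0.0265). Its level was low, 3.55 ± 0.24 (SD, n = 5) without and 4.18 ± 0.20 (SD, n = 4) with a-CD4. Bach2, a repressor of effector differentiation, fell by 1.08 (SE 0.26, adjusted p = 0.0403; lower in 4 of 4). With each array left out in turn, Foxp3 lost its call in 7 of 9 (adjusted p up to 0.0813, without SD-101+anti-PD-1 replicate 1) and Bach2 in 6 (0.158, without SD-101+anti-PD-1+a-CD4 replicate 2). Ncapg and Rrm1 lost theirs in 4 (0.109 and 0.0751 without SD-101+anti-PD-1+a-CD4 replicate 2), and Kif11 kept its call in all. The other largest rises were of the endothelial gene Gpihbp1 (3.10), Ier5l (2.06), Sema7a (1.95) and Ubd (1.93), followed by Penk (1.84) and Bcl2l15 (1.71). The largest falls included the ciliary genes Cfap126 (-2.33), Pifo (-2.32), Nme5 (-2.30) and Rsph1 (-2.26). Cckar (-2.31), Stab2 (-2.28), Arg1 (-2.26) and Cdhr4 (-2.24) were the others. With 1 array left out, calls ended for Gpihbp1, Sema7a, Ubd and Penk (in 6, 3, 3 and 3 of 9 fits, adjusted p up to 0.12, 0.069, 0.0757 and 0.0627 without SD-101+anti-PD-1+a-CD4 replicate 1) and Ier5l, Cfap126, Pifo, Cckar, Nme5 and Rsph1 (in 6, 8, 4, 7, 4 and 2 of 9 fits, adjusted p up to 0.113, 0.181, 0.0751, 0.123, 0.083 and 0.0645 without SD-101+anti-PD-1+a-CD4 replicate 2).

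Of 41 cell cycle genes, 8 rose and 33 did not pass, while 38 rose when adjusted within the list and 41 had positive values. The mean shift was 0.98 (camera adjusted p = 2.99e-25, 0.558 with estimated correlation, 0.0374 by fry). Spag5 (1.22) was a further member that rose. Glycolysis genes averaged 0.48 with Gapdh (0.58) rising of 17, 5 when adjusted within the list (camera adjusted p = 1.04e-05, 0.558 with estimated correlation, 0.068 by fry). Oxidative phosphorylation genes averaged 0.10 with none of 28 called (camera adjusted p = 0.00226, 0.613 with estimated correlation, 0.0853 by fry). Memory genes averaged -0.34 with Bach2 alone of 19 falling (camera adjusted p = 0.00226, 0.613 with estimated correlation, 0.0892 by fry). The shift was -0.16 with SD-101+anti-PD-1+a-CD4 replicate 2 left out (adjusted p = 0.0407). CD4 and regulatory markers averaged 0.41 with Foxp3 alone of 12 rising, 5 when adjusted within the list (camera adjusted p = 0.0035, 0.558 with estimated correlation, 0.068 by fry). Inhibitory receptors averaged 0.46 with none of 20 called (camera adjusted p = 0.0327, 0.775 with estimated correlation, 0.514 by fry). This shift was 0.42, 0.47, 0.41, 0.28, 0.86, 0.34 and 0.37 with SD-101+anti-PD-1 replicates 1, 2 and 4 and SD-101+anti-PD-1+a-CD4 replicates 1, 2, 3 and 4 left out in turn (adjusted p = 0.0621, 0.0602, 0.061, 0.368, 1.29e-08, 0.23 and 0.184). Interferon-gamma-linked genes averaged 0.23 with Psmb10 (0.46) rising of 26 (camera adjusted p = 0.00745, 0.672 with estimated correlation, 0.27 by fry). The mean value was 0.17 and 0.18 with SD-101+anti-PD-1+a-CD4 replicates 1 and 3 left out in turn (adjusted p = 0.105 and 0.116). IL-2 and STAT5 genes averaged -0.31 with none of 18 called (camera adjusted p = 0.00992, 0.696 with estimated correlation, 0.344 by fry). That value was -0.088 with SD-101+anti-PD-1+a-CD4 replicate 2 left out (adjusted p = 0.432). With cell type scores as covariates memory and IL-2 means were -0.20 and -0.093 and those of inhibitory receptors, interferon-gamma-linked genes and CD4 markers 0.89, 0.37 and 0.65 (camera adjusted p = 0.136, 0.649, 4.63e-07, 1.7e-05 and 7.91e-06). Fits without 1 array lost the calls of Spag5, Gapdh and Psmb10 (in 7, 5 and 6 of 9 fits, adjusted p up to 0.141, 0.109 and 0.189 without SD-101+anti-PD-1+a-CD4 replicate 2).

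Ciliated genes, an added list, fell in 9 of 13 cases (mean -2.004; camera adjusted p = 1.68e-15, 0.0435 with estimated correlation). T cell identity genes averaged -0.087 with none of 13 called (camera adjusted p = 0.693). This value was 0.30 with SD-101+anti-PD-1+a-CD4 replicate 2 left out (adjusted p = 0.00334). Neutrophil markers averaged 1.41 with none of 17 called (camera adjusted p = 0.0116, 0.775 with estimated correlation, 0.514 by fry). That shift was 0.56 with SD-101+anti-PD-1+a-CD4 replicate 1 left out (adjusted p = 0.451). Endothelial markers averaged 0.94 with none of 14 called, 5 when adjusted within the list (camera adjusted p = 3.59e-04, 0.668 with estimated correlation, 0.27 by fry). Lung epithelial markers averaged -0.67 with none of 21 called (camera adjusted p = 0.00226, 0.668 with estimated correlation, 0.27 by fry). B cell markers averaged -0.59 with none of 17 called (camera adjusted p = 0.00745, 0.668 with estimated correlation, 0.27 by fry). Fibroblast markers averaged -0.41 with Lum (-1.40) falling of 14 (camera adjusted p = 0.0204, 0.773 with estimated correlation, 0.495 by fry). The list mean was -0.31 and -0.29 with SD-101+anti-PD-1 replicate 2 and SD-101+anti-PD-1+a-CD4 replicate 3 left out in turn (adjusted p = 0.109 and 0.183). B cell and fibroblast means with cell type scores as covariates were -0.081 and -0.0034 (camera adjusted p = 0.232 and 0.846). Leaving out 1 array ended the calls of Lum (in 8 of 9 fits, adjusted p up to 0.163 without SD-101+anti-PD-1+a-CD4 replicate 2).

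With a-CD4 162 genes rose and 202 fell (3060 at an unadjusted p under 0.05), and 147 and 143 with arrays centred. Mki67 had a value of 0.89 (adjusted p = 0.0887; exact p = 0.00794) and Pdcd1 1.24 (adjusted p = 0.164; exact p = 0.0397). The other 9 fixed genes not called had adjusted p of 0.365 to 0.994. The count was 94 and 81 without SD-101+anti-PD-1 replicates 1 and 4, 84, 73 and 232 without SD-101+anti-PD-1+a-CD4 replicates 1, 2 and 4, and 62 without the 2 arrays of lowest T cell identity score. It was 149 above the median level, 1246 with array weights, 242 with a block on replicate number, 614 with the heat shock score as a covariate and 0 in limma with cell type scores (1403 unadjusted). Of 23 called genes named here 5 stayed called whichever array was left out, and 17 lost the call without SD-101+anti-PD-1 replicate 4. Cell type scores as covariates left 6 of 10 list calls.

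SD-101+anti-PD-1+a-CD4 vs Saline-CTRL was the secondary comparison (4 against 5 arrays). Genes of inhibitory receptors were among the largest rises: Lag3 (log2 fold change 2.92, SE 0.50, adjusted p = 0.00192), Cd160 (2.78, SE 0.47, adjusted p = 0.00192), Pdcd1 (2.60, SE 0.47, adjusted p = 0.00244) and Havcr2 (2.58, SE 0.60, adjusted p = 0.0139), which encodes TIM-3. The first 3 were above every saline array in 4 of 4 arrays and Havcr2 in 3 of 4. Mki67, a marker of cycling cells, rose by 1.77 (SE 0.27, adjusted p = 0.00101), in 4 of 4 arrays above every saline array. Of these 5 genes only Havcr2 lost its call with an array left out (adjusted p = 0.0517 without SD-101+anti-PD-1+a-CD4 replicate 1). The chemokine gene Ccl3 (2.44), Ubd (3.03), Serpina3n (2.84) and Sytl3 (2.47) completed the largest rises. The largest falls were Bpifa1 (-4.27), Aplnr (-3.22), Myct1 (-3.04), Acvrl1 (-3.003) and Aspn (-2.93), followed by Tek (-2.87), Clec14a (-2.82) and Ednrb (-2.82). Calls that ended with 1 array left out were those of Serpina3n and Bpifa1 (in 6 and 3 of 9 fits, adjusted p up to 0.0792 and 0.0539 without Saline-CTRL replicate 3) and Tek (in 2 of 9 fits, adjusted p up to 0.0669 without SD-101+anti-PD-1+a-CD4 replicate 4).

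Cell cycle genes rose in 34 of 41 cases, 40 when adjusted within the list, with Kif11 (1.90), Nusap1 (1.49) and Rrm2 (1.93). The mean was 1.39 (camera adjusted p = 3.83e-30, 0.0938 with estimated correlation, 6.95e-04 by fry). Interferon-stimulated genes rose in 16 of 28 (mean 0.97; camera adjusted p = 1.09e-17, 0.0938 with estimated correlation, 6.95e-04 by fry), with Isg20 (1.48) and Zbp1 (1.39). Interferon-gamma-linked genes rose in 17 of 26, with Gbp2 (1.16) and Irgm2 (1.45) (mean 0.84; camera adjusted p = 2.57e-17, 0.0888 with estimated correlation, 3.99e-05 by fry). Adjusted within the list, 22 and 20 rose. Cytotoxic genes rose in 10 of 27 cases, 12 when adjusted within the list, among them Gzmb (2.40), Gzmk (1.97), Tbx21 (1.67) and Klrk1 (1.72). Their mean was 0.64 (camera adjusted p = 1.51e-04, 0.314 with estimated correlation, 0.0228 by fry). Inhibitory receptor genes had 4 of 20 rising and 2 falling, and a mean of 0.66 (camera adjusted p = 0.0465, 0.83 with estimated correlation, 0.273 by fry). It was 0.62, 0.63, 0.69, 0.48, 1.06, 0.54 and 0.57 with Saline-CTRL replicates 1, 2 and 4 and SD-101+anti-PD-1+a-CD4 replicates 1, 2, 3 and 4 left out in turn (adjusted p = 0.0599, 0.0754, 0.0611, 0.373, 1.98e-06, 0.202 and 0.17). Memory and naive-associated genes fell in 7 of 19 cases, 11 when adjusted within the list. Klf2 (-1.51), S1pr1 (-1.44), Klf3 (-1.06) and Foxp1 (-0.90) were examples. Their mean was -0.58 (camera adjusted p = 1.64e-07, 0.0938 with estimated correlation, 0.00213 by fry). CD4 and regulatory markers had Tnfrsf4 (1.31), Foxp3 (0.59), Il10 (0.72) and Capg (0.90) rising of 12 (mean 0.46; camera adjusted p = 0.00725, 0.288 with estimated correlation, 0.0102 by fry). Cell type scores as covariates gave 0.20 and 0.27 for inhibitory receptors and CD4 markers (camera adjusted p = 0.841 and 0.386), and the heat shock score 0.72 for the latter (camera adjusted p = 0.00303). Single arrays left out ended the calls of Tnfrsf4 (in 1 of 9 fits, adjusted p up to 0.0539 without SD-101+anti-PD-1+a-CD4 replicate 4) and Foxp3 (in 1 of 9 fits, adjusted p up to 0.0565 without SD-101+anti-PD-1+a-CD4 replicate 3). With 1 array left out, calls ended for Il10 (in 4 of 9 fits, adjusted p up to 0.0814 without SD-101+anti-PD-1+a-CD4 replicate 1) and Capg (in 7 of 9 fits, adjusted p up to 0.164 without SD-101+anti-PD-1+a-CD4 replicate 2).

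Glycolysis genes rose in 4 of 17 cases, Pfkp (0.65), Hif1a (0.52), Hk1 (0.46) and Gapdh (0.51). Their mean was 0.41 (camera adjusted p = 4.17e-04, 0.314 with estimated correlation, 0.0228 by fry). The mean was 0.26 with SD-101+anti-PD-1+a-CD4 replicate 2 left out (adjusted p = 0.0107). Oxidative phosphorylation genes rose in 4 of 28, Sdhb (0.37), Cox5a (0.44), Cox5b (0.43) and Uqcrq (0.36). Their mean was 0.16 (camera adjusted p = 6.79e-05, 0.245 with estimated correlation, 0.00182 by fry). In the IL-2 and STAT5 list Pim1 (-1.09) and Mcl1 (-0.47) fell of 18 (mean -0.28; camera adjusted p = 0.00335, 0.496 with estimated correlation, 0.287 by fry). This mean was -0.062 with SD-101+anti-PD-1+a-CD4 replicate 2 left out (adjusted p = 0.256). Oxidative phosphorylation and IL-2 means with cell type scores were 0.084 and -0.44 (camera adjusted p = 0.355 and 4.38e-05), and the latter was -0.20 with the heat shock score (camera adjusted p = 0.109). Without SD-101+anti-PD-1+a-CD4 replicate 2 Pim1 was -0.70. Fits without 1 array lost the calls of Pim1, Mcl1 and Gapdh (in 4, 7 and 3 of 9 fits, adjusted p up to 0.106, 0.143 and 0.0715 without SD-101+anti-PD-1+a-CD4 replicate 2) and Uqcrq (in 7 of 9 fits, adjusted p up to 0.125 without Saline-CTRL replicate 3). Immediate early genes had 4 of 28 rising and 9 falling, among them Fos (-0.93), Egr1 (-1.19), Fosb (-2.68) and Dusp1 (-1.35). That list averaged -0.45 (camera adjusted p = 3.12e-05, 0.288 with estimated correlation, 0.0427 by fry). With the heat shock score as a covariate the mean turned to 0.047. Heat shock genes fell in 7 of 17 cases (mean -0.68; camera adjusted p = 4.03e-07, 0.146 with estimated correlation, 0.00728 by fry). The 18S control near the 5' end averaged 12.06 ± 0.081 (SD, n = 4) with SD-101+anti-PD-1+a-CD4 and 11.68 ± 0.29 (SD, n = 5) with saline, where replicates 1 and 2 had 11.99 and 11.998.

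Endothelial markers fell in 13 of 14 cases, with Vwf (-2.63), Calcrl (-1.99), Pecam1 (-1.86) and Esam (-1.50). Their mean was -1.92 (camera adjusted p = 4.58e-16, 0.0938 with estimated correlation, 0.00182 by fry). Erythroid markers averaged -0.49 with none of 9 called (camera adjusted p = 0.00683, 0.115 with estimated correlation, 0.018 by fry). With cell type scores and with the heat shock score as covariates this was -0.023 and -0.98 (camera adjusted p = 0.0819 and 0.00237). The gamma-delta list, with 5 measured members and no list call in any comparison on all arrays, averaged -0.65 (camera adjusted p = 0.0818). The value was -0.86, -0.85 and -0.10 with Saline-CTRL replicates 1, 2 and 5 left out in turn (adjusted p = 0.0423, 0.0257 and 0.688). Neutrophil markers averaged 1.23 with none of 17 called (camera adjusted p = 0.175). That was 2.45, 0.38 and 1.90 with Saline-CTRL replicate 1 and SD-101+anti-PD-1+a-CD4 replicates 1 and 3 left out in turn (adjusted p = 2.09e-07, 0.88 and 0.0124). In none of the called lists, of any comparison, did the mean, the median and the camera direction differ in sign. Among lists not called they did differ, as for immediate early genes in SD-101 vs Saline-CTRL (mean 0.00077, median -0.10) and erythroid markers in SD-101+anti-PD-1 vs SD-101 (mean -0.37, median 0.074).

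Here 700 genes rose and 518 fell (3560 at an unadjusted p under 0.05), a balance that turned to 357 and 534 with arrays centred, 555 and 609 after quantile normalization and 596 and 647 after cyclic loess. Cd274 rose by 0.97 (adjusted p = 0.0227; exact p = 0.0159), with a call lost in 2 of 9 fits without 1 array (adjusted p up to 0.0838, without SD-101+anti-PD-1+a-CD4 replicate 1). Prf1, the gene of perforin, had a value of 1.28 (adjusted p = 0.0716; exact p = 0.0952) and Ifng 1.22 (adjusted p = 0.196; exact p = 0.0873). The other 5 fixed genes had adjusted p of 0.232 to 0.993. The count was 665 without Saline-CTRL replicate 3, 476 with only these groups fitted and 2013 over every probe set. It was 7 with cell type scores as covariates, and 1408 with the heat shock score, of which 673 were among the 1218. Of 62 genes checked, not all named, 49 kept the call with any 1 array left out, and 9 lost it without Saline-CTRL replicate 3. Cell type scores left 9 of 13 list calls.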

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

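The tests of the endothelial, cell cycle and clock output patterns were chosen only after the results they measure had been seen; the counts of other splits were planned. For each of 156 groups of arrays, the gap between the highest or lowest array and its neighbour was taken as a share of the group's range. It passed Dixon's 95% limit in 14 groups, where chance alone gives about 5% of them, or 7.8.

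SD-101+anti-PD-1+a-CD4 replicate 2 was far below the other 3 arrays of its group in Cd8a (gap share 0.837), Cd8b1 (0.912) and Pdcd1 (0.858). It was also lowest in T cell identity (0.875), inhibitory receptors (0.846), tissue residency (0.938), IL-2 and STAT5 signalling (0.837) and lung epithelial markers (0.949). Its Cd8a value was 9.45 where the next lowest was 11.30, and its T cell identity score 8.85 where the next was 10.33. Saline-CTRL replicate 1 had a neutrophil score of 9.67 where the next highest was 3.604 (gap share 0.974), and the lowest Ifng of its group (0.805). Saline-CTRL replicate 5 was highest in interferon-stimulated genes (0.725) and gamma-delta markers (0.752). SD-101 replicate 2 was highest in cholesterol synthesis (0.676) and lowest in T cell identity (0.686). Among 15588 probe sets without a listed gene, which the comparisons did not use, 277 passed in SD-101+anti-PD-1+a-CD4 vs Saline-CTRL, 145 higher and 132 lower.

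Other splits of the arrays into groups of the same sizes gave as many called genes in 4 of 100 cases for SD-101 vs Saline-CTRL, the real split included, with 57 genes in the real split and 245 in the highest other. The splits were a draw from those possible, so a share this near 0.05 does not exclude chance. A split that calls several times the real count also points to a structure of the samples. That split set Saline-CTRL replicates 3 and 5 and SD-101 replicates 3, 4, 5 and 6 against the rest, with heat shock scores 0.38 higher. The share was 1 of 100 for SD-101+anti-PD-1 vs Saline-CTRL (962 genes, highest other 43). It was the same for SD-101+anti-PD-1 vs SD-101 (816, highest other 454), SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1 (364, 143) and SD-101+anti-PD-1+a-CD4 vs Saline-CTRL (1218, 629). The real split is counted, so 1 is the floor and chance is unlikely but not excluded. For SD-101+anti-PD-1 vs SD-101 the highest other split set SD-101 replicates 3 to 6 and SD-101+anti-PD-1 replicate 5 against the rest (heat shock gap 0.60). For SD-101+anti-PD-1+a-CD4 vs Saline-CTRL it set Saline-CTRL replicates 3, 4 and 5 and SD-101+anti-PD-1+a-CD4 replicate 2 against the rest (heat shock gap 0.72).

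The heat shock scores differed within 2 of the groups, a division similar to those splits but not the same. They were 9.58 and 9.51 in Saline-CTRL replicates 1 and 2 but 10.11 to 10.42 in replicates 3 to 5, and 9.34 and 9.69 in SD-101 replicates 1 and 2 but 9.999 to 10.10 in replicates 3 to 6. All SD-101+anti-PD-1 arrays lay between 9.03 and 9.34, and all SD-101+anti-PD-1+a-CD4 arrays between 9.08 and 9.51. By these scores Saline-CTRL replicate 4, SD-101+anti-PD-1 replicate 5 and SD-101+anti-PD-1+a-CD4 replicate 2 lay on the other side from the splits that placed them. The 18S control near the 5' end parted the saline arrays likewise. It did not part the SD-101 arrays (11.30 and 11.61 in replicates 1 and 2, 11.37 to 11.80 in replicates 3 to 6). The labels give no batch, so no fit has it as a term.

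Endothelial markers were lower with SD-101+anti-PD-1 than with saline, and a change in the share of T cell RNA would move all lung cells alike, but the endothelial shift minus the lung epithelial shift was -3.73 (exact p = 0.00794), with shifts of opposite sign. Within groups the endothelial genes varied together, with a median pairwise correlation across arrays of 0.867 against a 95th percentile of 0.171 for random lists of like level, in line with endothelial RNA that reached the arrays in differing amounts despite the CD8 sort. Tissue handling, read from the heat shock score, was first tested by its correlation with the endothelial score within groups, r = 0.0994 (permutation p = 0.738; rho = 0.00451, permutation p = 0.989; r = -0.0895 without the 2 farthest arrays), which decided nothing. With that score as a covariate over 20 arrays the endothelial shift was -2.68 (SE 0.62, exact p = 0.00794). Without the covariate it was -2.86 (SE 0.41). The lung epithelial shift went from 0.88 to -0.048. Calls of single endothelial genes went from 13 to 0 as their median SE rose from 0.43 to 0.63 (median size 3.33 and 3.05). Heat shock scores of the 2 groups did not overlap, so that covariate rested on the same slopes within groups and decided nothing further. Handling stays open, as does, untested, an effect of treatment on endothelium or on what the sort carried over.

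Cell cycle genes were higher with SD-101+anti-PD-1+a-CD4 than with saline. A larger share of T cell RNA was tested first by the cell cycle shift minus the T cell identity shift, 1.26 (exact p = 0.119), which decided nothing, and the correlation within groups was then taken up. Over 20 arrays the cell cycle score fell as the T cell identity score rose, r = -0.507 (permutation p = 0.0249, 0.0499 adjusted over 2 such relations; rho = -0.538, permutation p = 0.0291, 0.0583 adjusted; r = -0.438, permutation p = 0.178 without the 2 farthest arrays), which argues against a larger T cell share, by a narrow margin that did not hold without those 2 arrays. With the T cell identity score as a covariate the shift was 1.46 (SE 0.24, exact p = 0.0159) against 1.39 (SE 0.27) without it. Without those 2 arrays it was 1.64 (SE 0.33). Both fits only reuse that relation. The same r is what cycling cells other than T cells would give, so they stay a candidate explanation, and more division of the CD8 T cells themselves under this treatment is also open, untested.

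Clock output genes, an added list, shifted from saline to SD-101 by -0.80 (exact p = 0.00433). From SD-101 to SD-101+anti-PD-1 they shifted by 0.34 (exact p = 0.0823) while the endothelial score fell by 2.24. A lower share of endothelial RNA cannot be told apart by this, since the list was drawn up from genes low in the same SD-101 arrays, which favours a rise from there. Another time of day at collection cannot be told apart: the opposite-phase clock genes shifted by -0.016 (exact p = 0.874), while against saline they averaged 0.19 with SD-101+anti-PD-1+a-CD4 (camera adjusted p = 0.298, 1 of 5 rising), where clock output genes fell as well, and the labels give no hour. An effect of SD-101 on clock genes stays open, untested.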

How the results depend on the processing

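The alternatives that left out the 2 arrays of lowest T cell identity score or added list scores as covariates were chosen after seeing the data. Counts stayed within 1.5 times of the reported values with the mean of a gene's probe sets, quantile normalization, cyclic loess and the trended robust variance. Each array left out in turn gave 25 to 64 genes for SD-101 vs Saline-CTRL, 553 to 1531 for SD-101+anti-PD-1 vs Saline-CTRL, 317 to 1081 for SD-101+anti-PD-1 vs SD-101, 73 to 488 for SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1, 665 to 1234 for SD-101+anti-PD-1+a-CD4 vs Saline-CTRL, and 20 to 45 shared genes. The lowest values came without SD-101 replicate 5, Saline-CTRL replicate 3, SD-101+anti-PD-1 replicate 4, SD-101+anti-PD-1+a-CD4 replicate 2, Saline-CTRL replicate 3 and SD-101 replicate 3. In that order of comparisons, array weights gave 119, 1953, 2760 and 1246 genes in the first 4; fitting only the groups compared gave 10, 1332 and 476 for the first, SD-101+anti-PD-1 vs SD-101 and the last; and keeping genes above the median level gave 566, 325 and 149 in the middle 3, where fewer genes were tested. Centring gave 36 genes for SD-101 vs Saline-CTRL and 28 shared genes. Over every probe set 2013 passed in SD-101+anti-PD-1+a-CD4 vs Saline-CTRL. A block on replicate number gave 42, 1075, 751, 242 and 1268, although equal numbers did not pair the arrays. Without the 2 arrays of lowest T cell identity score SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1 had 62 genes, and the Saline-CTRL arrays split between comparisons left 6.5 shared genes. In SD-101+anti-PD-1 vs Saline-CTRL 476 genes rose and 453 fell after quantile normalization and 501 and 431 after cyclic loess. In SD-101+anti-PD-1+a-CD4 vs Saline-CTRL they were 555 and 609, 596 and 647 and, centred, 357 and 534. Beyond the smaller number of genes or arrays where that differs, the cause was not tested.

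With 4 cell type scores as covariates the counts were 0, 0, 0, 0 and 7 in limma, with 1192, 1149, 890, 1403 and 2058 at an unadjusted p under 0.05, and 0 shared genes. With the heat shock score the counts were 99, 1, 3 and 614 in the first 4, with 0 shared genes. The scores themselves differ between groups, so these fits remove group differences with them. For the 962 genes of SD-101+anti-PD-1 vs Saline-CTRL the median size went from 1.11 (median SE 0.24) to 0.51 (SE 0.41) with cell scores and 0.67 (SE 0.32) with the heat shock score, and 653 and 949 kept their direction. For the 57 genes of SD-101 vs Saline-CTRL it went from 1.17 (SE 0.20) to 0.94 (SE 0.26) with cell scores, all in their direction, so calls ended through smaller sizes and larger errors.

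Of the called lists and the called genes named in the text, values changed sign only under these added covariates; lists used as covariates have no value there. The T cell identity mean, not called, went from -0.087 to 0.30 in SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1 without SD-101+anti-PD-1+a-CD4 replicate 2. With cell scores in SD-101 vs Saline-CTRL the means were -0.12 for inhibitory receptors, -0.015 for tissue residency, -0.044 for chemokines, -0.00042 for TLR9 signalling, -0.056 for T cell identity, -0.021 for CD4 and regulatory markers and -0.10 for dendritic cells. In SD-101+anti-PD-1 vs Saline-CTRL they were 0.65 for Tek, 0.31 for Sema3g, -0.16 for Ccne1, 0.61 for Id3, -0.12 for Cldn7, -0.23 for Col1a1, -0.048 for Col3a1 and -0.032 for cytotoxic genes. In SD-101+anti-PD-1 vs SD-101 they were 0.24 for Tek, 0.11 for C1qa, -0.090 for Cldn7, -0.24 for cholesterol synthesis and -0.21 for fibroblasts, and in SD-101+anti-PD-1+a-CD4 vs Saline-CTRL 0.29 for Tek and 0.046 for Pecam1. With the heat shock score, immediate early genes, some held in it, had means of 0.093, 0.021 and 0.047 in SD-101+anti-PD-1 vs Saline-CTRL, vs SD-101 and SD-101+anti-PD-1+a-CD4 vs Saline-CTRL. Fibroblast markers had -0.045 and -0.066 in the first pair of these, lung epithelial markers -0.048 in the first and Cyp2f2 -0.067 in SD-101+anti-PD-1 vs SD-101. The cause of these reversals was not tested. Calls of lists also ended (camera adjusted p from limma in brackets) in SD-101 vs Saline-CTRL for oxidative phosphorylation when centred (0.0808) or after cyclic loess (0.244), TLR9 signalling after cyclic loess (0.057) or with only these groups fitted (0.0627), CD4 markers after quantile normalization (0.0508), with a block (0.0758) or without the 2 arrays of lowest T cell identity (0.0648), and T cell identity without them (0.0881). In SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1 they ended for inhibitory receptors when centred (0.0735) or above the median level (0.108), neutrophils above it (0.476), IL-2 genes with array weights (0.246) or without those 2 arrays (0.41) and fibroblasts with weights (0.0799). In SD-101+anti-PD-1+a-CD4 vs Saline-CTRL they ended for inhibitory receptors above the median level (0.172) or with only these groups fitted (0.0533) and IL-2 genes with weights (0.0925) or without those arrays (0.157). Cytotoxic genes lost theirs with weights in SD-101+anti-PD-1 vs Saline-CTRL (0.0889) and macrophage markers above the median level in SD-101+anti-PD-1 vs SD-101 (0.341). Of 67 list calls, 63 were lost with an estimated correlation. Genes near the lowest signals, such as Cd4 and Tlr9, lie close to background, where a change would be hard to see (the array lower quartile was 2.73).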

Other observations

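The tests here were chosen after the data were seen. Mast cell genes, an added list drawn up from genes among the largest changes, differed between groups. They averaged 1.004 in SD-101 vs Saline-CTRL, with 2 of 9 rising, Cma1 (2.57) and Mcpt2 (2.40) (camera adjusted p = 4.29e-07, 0.00514 with estimated correlation). Leaving out 1 array ended the calls of Mcpt2 (in 8 of 11 fits, adjusted p up to 0.118 without Saline-CTRL replicate 1). In SD-101+anti-PD-1 vs SD-101 6 of 9 fell, Mcpt2 (-3.601) among them, with a mean of -1.68 (camera adjusted p = 2.35e-12, 6.52e-04 with estimated correlation). In SD-101+anti-PD-1 vs Saline-CTRL 1 of 9 fell and the mean was -0.67 (camera adjusted p = 2.94e-04, 0.0378 with estimated correlation). Clock output genes, also added, fell in 3 of 8 cases in SD-101 vs Saline-CTRL (mean -0.80; camera adjusted p = 1.71e-13, 0.00113 with estimated correlation) and in 4 in SD-101+anti-PD-1+a-CD4 vs Saline-CTRL (mean -0.95; camera adjusted p = 2.49e-08, 0.0105 with estimated correlation). Of 8, 1 fell in SD-101+anti-PD-1 vs Saline-CTRL (mean -0.46; camera adjusted p = 7.20e-04, 0.067 with estimated correlation), while in SD-101+anti-PD-1 vs SD-101 3 of 8 rose (mean 0.34; camera adjusted p = 0.0153, 0.189 with estimated correlation). With a-CD4 against SD-101+anti-PD-1 the mean was -0.49, with 0 rising and 0 falling (camera adjusted p = 0.00111, 0.075 with estimated correlation). Opposite-phase clock genes, the fourth added list, had none of 5 called in SD-101 vs Saline-CTRL (mean -0.016, median 0.10; camera adjusted p = 0.825). Their mean was 0.35 with a-CD4 against SD-101+anti-PD-1 (camera adjusted p = 0.0485, 0.075 with estimated correlation), with 4 of 5 positive and none called. It was 0.19 in SD-101+anti-PD-1+a-CD4 vs Saline-CTRL (camera adjusted p = 0.298), with 5 of 5 positive and 1 rising, -0.16 in SD-101+anti-PD-1 vs Saline-CTRL and -0.14 in SD-101+anti-PD-1 vs SD-101 (camera adjusted p = 0.581 and 0.427, none called).

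SD-101+anti-PD-1 vs SD-101 and SD-101+anti-PD-1+a-CD4 vs SD-101+anti-PD-1 called 141 of the same genes in opposite directions, 134 of which rose in the first, and 0 in the same direction. The ciliary genes Pifo (2.80 and -2.32) and Nme5 (2.56 and -2.30) were among them. Calls that ended with 1 array left out were those of Pifo and Nme5 (in 4 and 4 of 9 fits, adjusted p up to 0.0751 and 0.083 without SD-101+anti-PD-1+a-CD4 replicate 2). Both comparisons use the SD-101+anti-PD-1 arrays, with opposite signs, which alone favours opposite changes. Simulated unchanged groups shared a median of 0 and at most 0 with those arrays on both sides, a value without real effects, and independent calls would share 7.11 and 2.03, a value without shared arrays. The correlation across genes was -0.607, inside the range of -0.85 to 0.199 (median -0.513) of simulated unchanged groups, and the covariance was -0.121 against a simulated mean of -0.0299. With those arrays split between the comparisons, the median over 20 splits was 12 genes (range 0 to 52). SD-101+anti-PD-1 and SD-101+anti-PD-1+a-CD4 shared 370 calls of the same direction against saline (simulated median 0, highest 162, 24.3 rising and 11.1 falling if independent). SD-101 and SD-101+anti-PD-1+a-CD4 shared 40 (simulated median 0, highest 1, 2.09 rising and 0.182 falling if independent). With the saline arrays split between the comparisons the medians were 86.5 (range 28 to 165) and 7 (range 1 to 46).

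The closest pair of arrays, SD-101+anti-PD-1 replicates 1 and 4, had a correlation of 0.993 across genes, the lowest of any pair was 0.927, and 0 columns were identical. Probe sets without a listed gene passed in 19, 201, 77 and 32 cases in the other 4 comparisons, in the order of the text.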
